A study of Yarrowia lipolytica with 9 samples.

How the data were processed

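Total RNA of 3 engineered strains of the oleaginous yeast Yarrowia lipolytica was sequenced, with 3 libraries for each strain and 9 in all. Per the labels, the strains are named yl_10, yl_11 and yl_12, descend from 1 host strain and carry heterologous genes. The cells were grown in shake flasks for 72 h at 28 °C and 250 rpm, then pelleted and frozen in liquid nitrogen. Libraries were made with an NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq instrument as paired-end reads of 150 bp, per the labels' protocols. The labels say that the series compares strains with different levels of lycopene, the red carotenoid, as end product. They tie no lycopene level to a strain and name no parent or control strain, so each pair of strains was compared and each fold is named by its strains.

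The authors deposited a table of read counts and a table of FPKM values, each with 1 column per library. The deposited read counts are whole numbers that were not normalised. HTSeq 0.6.1 and DESeq 1.18.0 are named in the submitters' processing notes, with no role given. The aligner, the genome build, the annotation release and the use of strand in counting are not given in the sources used here. Reads of overlapping genes, of antisense genes and of near-identical copies may therefore have been split or lost, and this cannot be checked from the tables. The deposited FPKM values, which are fragment counts scaled to transcript length and library size, equal the count divided by length and by library total, with a largest relative difference of 7.105e-15. They hold no composition factor. They served as an alternative to the counts and gave the length of each feature.

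The tables hold 6366 features, of which 5959 carry RefSeq transcript accessions and 407 carry a running number given by the authors. A count of 0 in all 9 libraries was found for 44 features. The lengths behind the FPKM values were multiples of 3 for 100% of the 5937 RefSeq features with a length, so they are coding lengths. The lengths of features with a running number are not. Accessions were matched without their version to the RefSeq gene table of assembly ASM176148v1, and 5430 of them (91.1%) matched. An exact match with the version was found for 619. That table gave locus tags and the order of genes, and no product names. Because the build of the authors is not stated, none of its coordinates are printed.

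Before the data were examined, 23 gene lists with 96 locus tags were fixed, covering isoprenoid, sterol, lipid, central carbon and stress pathways. The lists use an older tag series than the table, and 0 of the 96 tags could be matched to a feature. The tests of these lists were therefore not run, and no pathway is reported here. Under the rule fixed in advance for this case, the text names per comparison the 2 features with the largest rise and the 2 with the largest fall. They had to have an adjusted p below 0.05, a mean of at least 10 CPM (counts scaled to library size) in the higher strain and no overlap between the libraries of both strains. Any other feature named was chosen after its values were seen.

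Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter by strain and robust dispersion estimates. All 9 libraries entered 1 fit with strain as the only term, so that the 3 pairwise contrasts shared 1 estimate of the spread. An F test in the same fit asked whether a gene differed among the 3 strains. After the filter 6147 features were tested, of which 5788 were RefSeq transcripts and 359 were features with a running number. P-values were adjusted by the Benjamini-Hochberg method, and a feature was called at an adjusted p below 0.05. Adjusted p-values in the text come from this test unless another is named. Values per strain are means of CPM with the SD over 3 libraries, and fold changes are on the log2 scale with their standard error (SE).

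Nothing in the labels says that the 3 libraries of a strain came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Every pair of libraries within a strain differed by more than counting noise, with a chi-square per degree of freedom from 1.74 to 15.6, and none was counted as a repeat deposit. On simulated counts with 100 changed features per size, the test recovered 73% of changes of 0.5 and 92% of changes of 1 on the log2 scale for yl_11 against yl_10. The shares were 74% and 92% for yl_12 against yl_10, and 73% and 93% for yl_12 against yl_11. Unchanged features made up 9.84%, 4.05% and 9.29% of the calls in these 3 simulations, against a nominal share of 5% implied by the threshold of 0.05. The simulated counts were drawn independently for each feature and library. They lack the deviation that 1 library of each strain shared, described in the Results, so the shares may differ in these data.

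Neighbouring pairs of genes called in the same direction were counted over the 5342 tested genes with a locus tag and compared with 10000 shuffles of the calls. Calls shared by comparisons with a common strain were set beside 20 simulations without any effect. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma 3.58.1 on log2 FPKM with pseudocounts of 1 and 0.1, fits of the 6 libraries compared, a replicate block and each library left out in turn. After the data were seen, 2 alternatives to the fit were added because 1 library of each strain stood apart from the others. One left these 3 libraries out and the other gave them a term in the fit.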

Results

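Transcript levels were measured by RNA sequencing in 3 engineered Yarrowia lipolytica strains, with 3 libraries per strain. Library totals were 14100668, 8304873 and 7035777 counts for yl_10, 16424183, 12094446 and 10995778 for yl_11, and 11826987, 12471651 and 12461559 for yl_12. The 10 most abundant features took between 8.39% and 9.46% of the counts of a library, and TMM factors lay between 0.970 and 1.03.

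The first principal component of log2 CPM held 33.0% of the variance and ordered the strains, while the second held 22.4%. Within each strain 1 library stood apart from the other 2: yl_10 replicate 3, yl_11 replicate 1 and yl_12 replicate 3. Their deviations from the strain means correlated with each other across 3658 features, with r from 0.30 to 0.66. These 3 libraries were picked from their own values, as the library of each strain with the lowest mean correlation to the other 2.

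**Figure D1:**
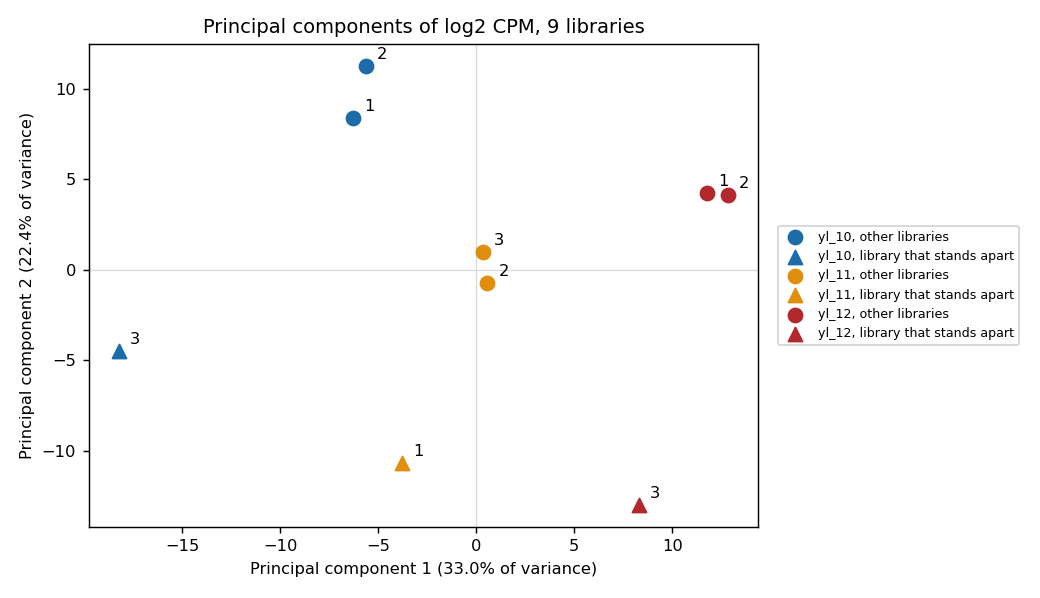
Principal components 1 (33.0% of the variance) and 2 (22.4%) of log2 CPM, with 1 point per library, coloured by strain and numbered by replicate. Triangles mark yl_10 replicate 3, yl_11 replicate 1 and yl_12 replicate 3, which lie lower on component 2 than the other 2 libraries of their strain.

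The 3 strains differed in 920 of 6147 features in the F test of edgeR at an adjusted p below 0.05. Mean levels in yl_11 lay between those of the other strains for 566 of the 920 (61.5%). A feature that differs in yl_10 or yl_12 alone can also place yl_11 in the middle, so this share does not measure a graded change. Of these, 272 rose from yl_10 through yl_11 to yl_12 and 294 fell. For the remaining features yl_10 was in the middle in 200 and yl_12 in 154. Leaving out 1 library moved the count of 920 by over 1.5 times for yl_10 replicate 1 (600 features), yl_12 replicate 1 (558) and yl_12 replicate 2 (547). The share with yl_11 in the middle ranged from 51.9% (without yl_12 replicate 3) to 69.3% (without yl_11 replicate 1) over the 9 fits with 1 library left out. It was 51.1% without the 3 libraries that stand apart and 53.8% with a term for them.

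The comparison of yl_12 with yl_10 gave the largest number of calls, and its leading gene was YALI1_F26427g (XM_505640.1). Its level was 37.1 ± 3.4 CPM (SD, n = 3) in yl_10 and 203 ± 20 CPM in yl_12, a log2 fold change of 2.46 (SE 0.11, adjusted p = 6.29e-07 in edgeR). XM_505464.1, which has no locus tag, rose from 6.58 ± 2.21 to 21.9 ± 2.5 CPM, a log2 fold change of 1.70 (SE 0.20, adjusted p = 0.00019). Among the falls, YALI1_F25382g (XM_505603.1) went from 77.5 ± 15.2 to 18.4 ± 9.0 CPM, a log2 fold change of -2.06 (SE 0.44, adjusted p = 0.025). YALI1_F08585g (XM_505048.1) went from 97.53 ± 31.8 to 24.3 ± 9.8 CPM, a log2 fold change of -1.99 (SE 0.41, adjusted p = 0.021). The call of YALI1_F25382g was lost without yl_10 replicate 1 (adjusted p = 0.057), replicate 2 (0.057) or replicate 3 (0.056), without yl_12 replicate 1 (0.087) or replicate 2 (0.089), and with the replicate number as a block (0.060). That of YALI1_F08585g was lost without yl_12 replicate 1 (0.081) or replicate 2 (0.072).

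In all, 430 features were higher and 480 lower in yl_12 than in yl_10, with a median absolute log2 fold change of 0.34. Of these 910 calls, 56 reached a 2-fold change, 25 higher and 31 lower. The count of higher features was 280 without yl_10 replicate 1, 279 without yl_12 replicate 1 and 266 without yl_12 replicate 2. With library totals as the only scaling, 264 were higher and 791 lower, so the balance of directions depended on the scaling while the median log2 fold change of all features stayed within 0.1 of 0. Without the 3 libraries that stand apart, 1920 features were called. That choice removes the least similar library of each strain and so lowers the spread by construction. It gave the highest count of all 27 ways to leave out 1 library per strain, of which the other 26 ranged from 157 to 1359 with a median of 496.5. Of the 910 calls from all 9 libraries, 871 were among those of the 6 libraries under the same filter. These 6 libraries are part of the 9 and were left by a choice that lowers the spread. Most calls were therefore likely to recur.

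Abundant transcripts moved up more often than others. Of the 615 most abundant features, which had at least 348 CPM on average and held 61.3% of the counts, 119 were higher and 52 lower in yl_12 than in yl_10. Among the other features 311 were higher and 428 lower, and the directions differed by Fisher's exact test (adjusted p = 6.16e-10 over 6 tests). The share of higher calls was 69.6% against 42.1%, and with library totals only it was 52.0% against 19.7%. These tests take genes as units, which are not independent replicates. Abundant features named here were chosen after their values were seen. XM_503602.1 rose from 1095 ± 129 to 2532 ± 391 CPM, YALI1_B29419g (XM_501224.1) rose from 224 ± 47 to 638 ± 13 CPM, and YALI1_F14495g (XM_505264.1) fell from 1227 ± 86 to 570 ± 78 CPM.

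Genes called in the same direction lay next to each other more often than shuffled calls did. In yl_12 against yl_10 there were 119 neighbouring pairs, where 10000 shuffles gave 64.0 on average (permutation p = 0.0001, the smallest they can give, and adjusted p = 0.0003 over 9 tests). The pairs numbered 59 without yl_10 replicate 1, 65 without yl_12 replicate 1 and 62 without yl_12 replicate 2, and their ratio to random placement was 1.65 to 2.18 over the 9 fits with 1 library left out. Without the 3 libraries that stand apart this ratio was 1.30, with 359 pairs. Runs of at least 3 neighbours numbered 16, and the longest held 5 genes from YALI1_F26313g to YALI1_F26519g, chosen after the values were seen. Runs were not counted in the shuffled calls. Neighbours are tested genes with a locus tag, so other genes may lie between them. Around YALI1_F26427g, the log2 fold changes were 0.31 (SE 0.07) for YALI1_F26313g, 0.72 (SE 0.07) for YALI1_F26367g, 0.43 (SE 0.08) for YALI1_F26399g and 0.79 (SE 0.13) for YALI1_F26519g. The next gene, YALI1_F26574g, went the other way, with a log2 fold change of -1.17 (SE 0.11). It was also lower in yl_11 than in yl_10, at -0.96 (SE 0.11, adjusted p = 0.0025). Neither YALI1_F26574g (-0.21, adjusted p = 0.318) nor YALI1_F26519g (0.34, adjusted p = 0.172) was called in yl_12 against yl_11. In yl_12 against yl_10 the call of YALI1_F26313g was lost without yl_10 replicate 1 (adjusted p = 0.052). A second run, YALI1_E15555g, YALI1_E15559g and YALI1_E15583g, fell by 1.46, 1.12 and 0.90 on the log2 scale, and its members kept their calls in every alternative. Many other runs were less stable. Members of these lost their calls in up to 15 of the 22 alternatives (YALI1_E18514g), followed by 14 (YALI1_C30235g).

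**Figure D2:**
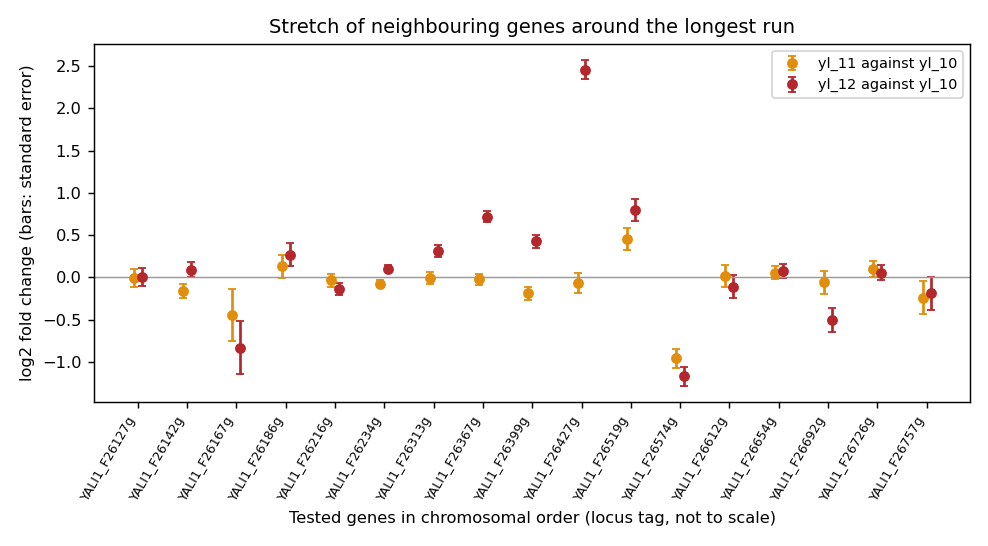
Log2 fold change (y axis, bars are standard errors) of 17 tested neighbouring genes in chromosomal order (x axis, not to scale) for yl_11 and yl_12, each against yl_10. In yl_12 the 5 genes from YALI1_F26313g to YALI1_F26519g are raised, with a peak of 2.46 at YALI1_F26427g, which was at -0.06 in yl_11. YALI1_F26519g was at 0.45 in yl_11 and 0.79 in yl_12, and the next gene, YALI1_F26574g, at -0.96 and -1.17.

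Between yl_11 and yl_10 fewer features were called, and more of the falls than of the rises reached a 2-fold change. YALI1_F07630g (XM_505015.1) fell from 39.2 ± 3.3 CPM (SD, n = 3) to 12.6 ± 2.8 CPM, a log2 fold change of -1.64 (SE 0.17, adjusted p = 0.00064 in edgeR). YALI1_B28430g (XM_501196.1) fell from 20.4 ± 0.7 to 6.68 ± 0.73 CPM, a log2 fold change of -1.60 (SE 0.12, adjusted p = 1.97e-05). The largest rises under the naming rule were XM_501880.1, from 8.07 ± 0.51 to 14.9 ± 0.7 CPM (log2 fold change 0.88, SE 0.10, adjusted p = 0.00064), and the feature Novel00075, from 31.8 ± 1.4 to 58.8 ± 2.2 CPM (0.88, SE 0.07, adjusted p = 1.97e-05). YALI1_C00464g (XM_501284.1), chosen after its values were seen, was at 927 ± 65 CPM in yl_10 and 323 ± 5.0 CPM in yl_11, a log2 fold change of -1.52 (SE 0.05). Levels in yl_12 were close to those in yl_11 for YALI1_F07630g (13.9 CPM), YALI1_B28430g (8.16 CPM) and XM_501880.1 (15.6 CPM). For these features yl_10 was the strain that differed. Novel00075 (34.0 CPM in yl_12) and YALI1_C00464g (805 CPM) were nearer to yl_10.

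There were 103 higher and 153 lower features in yl_11 against yl_10, and 10 of the 256 calls reached a 2-fold change, 1 higher and 9 lower. With library totals only, the share of higher calls went from 40.2% to 25.2%. The count of 256 depended on which libraries were included, and leaving 1 out also leaves fewer libraries to detect a change. It was 74, 103 and 97 without yl_10 replicate 1, yl_10 replicate 2 and yl_11 replicate 1, then 63, 106 and 166 without yl_11 replicate 2, yl_11 replicate 3 and yl_12 replicate 2, and 519 without yl_12 replicate 3. Without the 3 libraries that stand apart it was 1235, again the highest of the 27 choices, and the other 26 ranged from 8 to 932 with a median of 42.5. Among the most abundant features 30 were higher and 18 lower, against 73 and 135 of the others (Fisher's exact test, adjusted p = 0.0028), and with library totals only the abundant ones turned to a majority of falls, at 41.2% higher. These numbers of higher and lower abundant features were 9 and 7, 13 and 9, and 47 and 17 without yl_10 replicate 1, 2 or 3. They were 10 and 7, 7 and 5, and 8 and 6 without yl_11 replicate 1, 2 or 3, and 16 and 11, 15 and 12, and 75 and 30 without yl_12 replicate 1, 2 or 3. The share of higher calls among them was 55.6% to 73.4% in these fits, against 29.4% to 41.3% among the others. Neighbouring pairs numbered 17 against 5.33 in shuffled calls (permutation p = 0.0001, the smallest possible), at 3.20 times random placement. They numbered 5 without yl_10 replicate 1 or yl_11 replicate 2, 7 without yl_11 replicate 1 or 3, 9 without yl_10 replicate 2 and 40 without yl_12 replicate 3, and the ratio was 1.99 to 14.6 over the 9 fits with 1 library left out. Without the 3 libraries that stand apart this ratio was 1.24, with 140 pairs. With a term for them it was 1.35, with 65 pairs. Of 3 runs of neighbours in the fit of all 9 libraries, 2 fell and 1 rose. The falls were -1.60, -0.78 and -0.47 on the log2 scale for YALI1_B28430g, YALI1_B28454g and YALI1_B28472g, and -1.11, -0.77 and -0.21 for YALI1_E15555g, YALI1_E15559g and YALI1_E15583g. The call of YALI1_E15583g was lost without yl_10 replicate 1 (adjusted p = 0.073) and without yl_11 replicate 1 (0.065), 2 (0.089) or 3 (0.088). The run that rose was YALI1_B00049g, YALI1_B00082g and YALI1_B00133g, with log2 fold changes of 0.69 (SE 0.08), 1.57 (SE 0.24) and 0.75 (SE 0.08). The middle gene was scarce, at 1.09 CPM in yl_10 and 3.37 CPM in yl_11, and DESeq2 gave it no adjusted p.

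Of 178 features called against yl_10 in both yl_11 and yl_12, 175 went in the same direction and 3 in opposite directions. Both strains were higher than yl_10 in 69 features and lower in 106. Independent lists of these sizes would share 7.21 and 11.9, and 20 simulations without an effect gave 0 and 0.05. Neither count measures an excess. Few features can be called without an effect, so the simulated counts are near 0 in advance. The independent lists ignore that both comparisons use the yl_10 libraries. The covariance of the log2 fold changes was 0.0372 against 0.0122 in the simulations, and r across features was 0.60 against 0.52. The 3 libraries of yl_10 cannot give each comparison 2 of its own, and part of the shared calls and of the covariance may come from them. When yl_10 was divided 1 against 2 libraries between the comparisons, a check added after the data were seen, the covariance of log2 CPM differences over the 6 divisions was 0.0174 to 0.0264 and r was 0.20 to 0.37. With all 3 libraries in both, they were 0.0379 and 0.61 on this scale.

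The comparison of yl_12 with yl_11 was again led by YALI1_F26427g, at 35.1 ± 5.1 CPM (SD, n = 3) in yl_11 and 203 ± 20 CPM in yl_12, a log2 fold change of 2.52 (SE 0.11, adjusted p = 4.83e-07 in edgeR). YALI1_C00464g was higher in yl_12, at 805 ± 16 CPM against 323 ± 5.0 CPM, a log2 fold change of 1.32 (SE 0.05, adjusted p = 3.47e-08). With 927 CPM in yl_10, this gene stood out by its low level in yl_11. YALI1_E23790g (XM_504164.1) fell from 35.6 ± 1.7 to 10.4 ± 0.4 CPM, a log2 fold change of -1.78 (SE 0.09, adjusted p = 3.32e-07). YALI1_C18209g (XM_501783.1) went from 19.6 ± 4.9 to 7.68 ± 2.69 CPM, a log2 fold change of -1.36 (SE 0.27, adjusted p = 0.020), and this call was lost without yl_12 replicate 1 (0.088) or replicate 2 (0.076). The run YALI1_B00049g to YALI1_B00133g was lower in yl_12 than in yl_11, with log2 fold changes of -0.80 (SE 0.08), -2.15 (SE 0.25) and -0.76 (SE 0.07). Means in yl_12 and yl_10 were close, at 22.7 and 24.6, 0.75 and 1.09, and 74.9 and 75.6 CPM. This is therefore the rise in yl_11 given above, seen from yl_12. DESeq2 gave the scarce middle gene no adjusted p here either.

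**Figure D3:**
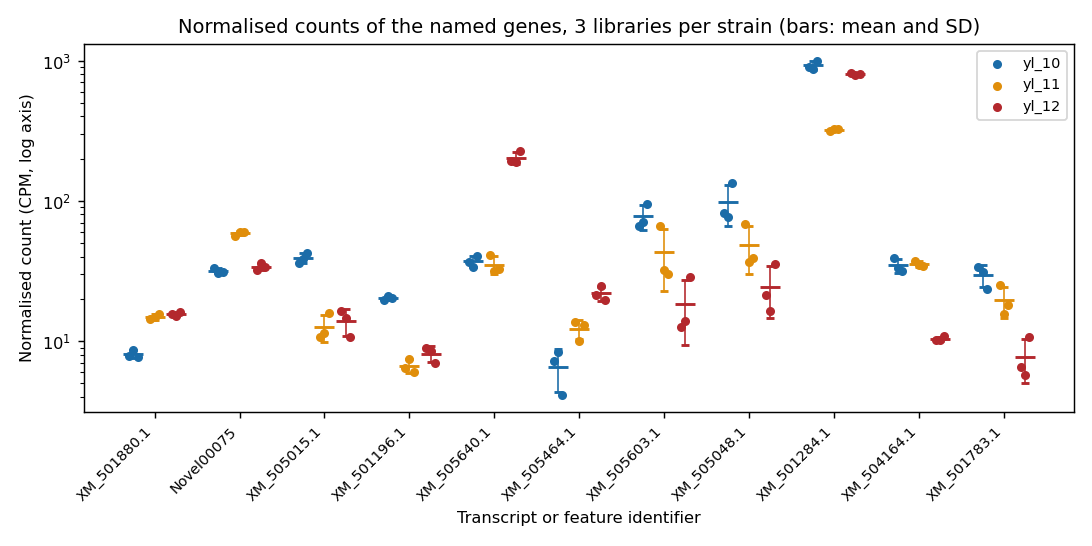
Normalised counts (CPM, log axis) of the 11 features named by the rule, with 1 point per library, and a dash and bar for the mean and SD of the 3 libraries of a strain. XM_505640.1 (YALI1_F26427g) stands at 203 CPM in yl_12 against 37.1 and 35.1 CPM in yl_10 and yl_11.

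In yl_12 against yl_11, 197 features were higher and 236 lower, and 20 of the 433 calls reached a 2-fold change, 7 higher and 13 lower. With library totals only, the share of higher calls went from 45.5% to 28.0%. The count of 433 was 201, 227 and 229 without yl_11 replicate 1, 2 or 3, and 193, 190 and 718 without yl_12 replicate 1, 2 or 3. Without the 3 libraries that stand apart it was 1514, the highest of the 27 choices, while the other 26 ranged from 46 to 1331 with a median of 166.5. Among the most abundant features 46 were higher and 30 lower, against 151 and 206 of the others (Fisher's exact test, adjusted p = 0.0076), and with library totals only 47.1% of the abundant calls were higher. The abundant calls were also nearly balanced, at between 46.3% and 48.8% higher, without any 1 of yl_11 replicate 1, 2 or 3 or yl_12 replicate 1 or 2. The higher and lower abundant features then numbered 19 and 22, 21 and 22, 21 and 22, 18 and 20, and 19 and 21. They numbered 76 and 35 without yl_10 replicate 3, and 73 and 52 without yl_12 replicate 3. Over the 9 fits with 1 library left out, the share of higher calls among abundant features exceeded that among the others by at least 8.3 points. The 2-fold count was 13 without yl_11 replicate 1 or yl_12 replicate 1 and 32 without yl_12 replicate 3. YALI1_F02132g (XM_504857.1), an abundant feature chosen after its values were seen, fell from 3916 ± 126 to 2054 ± 196 CPM. There were 30 neighbouring pairs against 14.9 in shuffled calls (permutation p = 0.0004). They numbered 13, 15 and 14 without yl_11 replicate 1, 2 or 3, 11, 13 and 61 without yl_12 replicate 1, 2 or 3, and 56 without yl_10 replicate 3, and the ratio to random placement was 1.57 to 4.31 over the 9 fits with 1 library left out. Without the 3 libraries that stand apart this ratio was 1.32, with 222 pairs. With a term for them it was 1.48, with 107 pairs. In the fit of all 9 libraries, calls shared with yl_12 against yl_10 numbered 140 higher and 178 lower. Independent lists would share 13.8 and 18.4, and simulations without an effect gave 0 in both directions. As above, neither count measures an excess. Few features can be called without an effect, and both comparisons use the yl_12 libraries. The covariance was 0.0428 against 0.0112 in the simulations. With yl_12 divided 1 against 2 libraries in the same way, the covariance was 0.0160 to 0.0394 and r was 0.18 to 0.57, against 0.0424 and 0.66 undivided. Part of the shared calls and of the covariance may again come from the shared libraries.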

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

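With library totals only, 66 features were higher in yl_11 than in yl_10, 264 were higher and 791 lower in yl_12 than in yl_10, and 115 were higher in yl_12 than in yl_11. The FPKM values carry the same scaling, and limma on them gave 55, 260, 747 and 84 in that order with a pseudocount of 1, 55, 259, 748 and 83 with a pseudocount of 0.1, and 42, 252, 741 and 77 without a filter. DESeq2 called 155 features higher in yl_11 than in yl_10. With the replicate number as a block, 59 were higher and 92 lower in that comparison, and the other counts of higher and lower calls stayed within 1.5 times. No pairing by number was seen. Libraries with the same number had deviations correlated from -0.55 to 0.36, and 0 of 9 libraries correlated best with their own number. The deviation shared by the 3 libraries that stand apart, whose numbers are not all alike, was not removed. A weaker pairing by number can therefore not be excluded. Over the 9 fits with 1 library left out, yl_11 against yl_10 gave 22 to 246 higher and 41 to 273 lower, yl_12 against yl_10 gave 266 to 507 higher and 335 to 505 lower, and yl_12 against yl_11 gave 67 to 370 higher and 118 to 348 lower. The F test gave 547 to 1232.

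The remaining alternatives were chosen after seeing the data. Without the 3 libraries that stand apart, the counts of higher and lower features were 624 and 611, 960 and 960, and 803 and 711 in the 3 comparisons, and 2357 in the F test. With a term for those libraries they were 355 and 452, 714 and 752, and 541 and 433, and 1704 in the F test. Both rest on libraries picked for their deviation, which lowers the spread, and the F test gave 130 to 1911 under the other 26 choices of 1 library per strain. How much of the larger counts comes from this choice, and how much from a difference shared by the 3 libraries, was not separated. Of the 12 results for features named by the rule, 9 stayed past the threshold in all 22 alternatives run on them. Over 97 results for single features and 2134 alternatives, the call was kept in 1941, lost in 193 and reversed in 0. All 97 were picked from the calls of the main fit of the same libraries. Kept calls and a lack of reversals were therefore likely in advance. Alternatives for the gene list tests were not run, since no list could be matched.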

Other observations

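The tests of depth and of far neighbours were set before their results were seen, as were the splits of the libraries, and the other tests here were chosen after.

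XM_500563.1 had 145 counts in yl_10 replicate 1 and at most 5 in each of the other 8 libraries, and it was not in the test. Features with a running number were called less often than RefSeq transcripts in yl_12 against yl_10, at 8.64% against 15.2% (Fisher's exact test, adjusted p = 0.00061 over 6 tests), and in yl_12 against yl_11, at 3.62% against 7.26% (adjusted p = 0.0090). In yl_11 against yl_10 the shares were 2.51% and 4.27%, and the test did not pass (adjusted p = 0.132). Their called members were 8 higher and 1 lower in yl_11 against yl_10, 88.9% higher against 38.5% of the RefSeq calls (adjusted p = 0.0069), and 21 higher and 10 lower in yl_12 against yl_10, 67.7% against 46.5% (adjusted p = 0.032). With library totals only they were 5 and 5, and 12 and 17, and without the 3 libraries that stand apart 40 and 20, and 37 and 47, so the direction in yl_12 against yl_10 turned under both, as it did with limma on FPKM and a pseudocount of 1 or 0.1 (12 and 19) or no filter (12 and 17). With 1 library left out they were 3 to 19 higher and 0 to 3 lower in yl_11 against yl_10, the most without yl_12 replicate 3, and 12 to 24 higher and 3 to 13 lower in yl_12 against yl_10, the fewest higher without yl_12 replicate 1. In yl_12 against yl_11 there were 6 higher and 7 lower, 46.2% against 45.5% (adjusted p = 1). Across the 5788 tested RefSeq features, which are not independent replicates, Spearman's rho of the log2 fold change with coding length was -0.20 for yl_11 against yl_10, -0.07 for yl_12 against yl_10 and 0.12 for yl_12 against yl_11. No fit corrected for length. Among the features named by the rule, XM_501880.1, XM_505464.1 and YALI1_C18209g were short, with coding lengths of 150, 168 and 183 bp.

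One library of each strain deviated along a shared axis. Unequal depth is argued against, since after thinning all libraries to 7035777 counts the lowest correlation among the 3 was still 0.288, and the deviation did not follow feature length (rho = 0.00067 over 6147 features, and 0.0014 with coding length over the 5788 RefSeq features). A shared batch or culture difference may lie behind the lowest correlation of 0.302, and it cannot be told apart from other causes because the labels give no batch or day. The features called in the other 6 libraries were compared in sign with these 3 libraries. The same sign was found for 82.6% in yl_11 against yl_10, 78.6% in yl_12 against yl_10 and 82.8% in yl_12 against yl_11. A share of 50% is no valid reference here, because features vary together and are not independent replicates. These 3 libraries hold no repeat of any strain, and libraries of a strain may share a culture. The shares therefore do not show independent replication of the strain differences. No biological explanation was tested.

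Neighbouring genes were called in the same direction in yl_12 against yl_10. Chance placement is argued against by the shuffles (permutation p = 0.0001, the smallest possible). They do not tell a strain difference from other variation that neighbours share between libraries. Reads shared between close genes are argued against as the only cause. Pairs with a gap above the median numbered 66 against 32.1 in shuffled calls (permutation p = 0.0001). Shared reads may still add to the closer pairs, 53 against 32.0 (permutation p = 0.0004). Gaps were taken between tested genes, in an assembly that may differ from the authors' build. No gain or loss of a block of 30 or more genes was seen, as the largest median of 30 neighbours was 0.14 on the log2 scale. A difference in local regulation, or a change at a site of integration, may be behind the run around YALI1_F26427g, and neither was tested.

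Other splits of the libraries were fitted. For yl_11 against yl_10, 1 of 10 splits gave as many calls, the real one with 256, and the highest of the others gave 0. For yl_12 against yl_10 it was 1 of 10, with 910 and 1, and for yl_12 against yl_11 1 of 10, with 433 and 0. With 10 splits no share below 0.05 can be reached. For the F test 1 of 100 splits drawn from 280, the real one, gave 920 features. This argues against a chance division of these 9 libraries but does not exclude it. The other splits mix strains, so strain differences enter their spread and lower their counts. Differences between single cultures of the strains cannot be excluded, since the labels do not say that libraries came from separate cultures. The highest of the others gave 235 and kept the 3 libraries of yl_12 together.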
